A study of Escherichia coli str. K-12 substr. MG1655 with 6 samples.

How the data were processed

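RNA had been sequenced from wild-type Escherichia coli K-12 MG1655 treated with sodium arsenite for 30 min at 37 °C, in 3 libraries of aggresome RNA and 3 of cytosol RNA, per the labels. Reads were aligned with BWA 0.7.17-r1188, per the submitters' processing notes. The read counter, the annotation, the genome build, the strand setting and any removal of rRNA are not given in the sources used here. The authors deposited 1 table of 1168 genes, whose first block of columns held whole-number read counts per gene and library. The second block held a normalized signal, which equalled the deposited counts divided by 1 size factor per library. The deposited table also held the authors' comparison of the fractions, with a log2 fold change and its standard error, a test score, a p-value and an adjusted p-value, and a call of higher, lower or not changed, per the file headers. The authors' size factors equalled those that DESeq2 computes from these 1168 genes, to within 2.9e-09%.

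Every gene of the deposited count table had at least 10 reads in 1 or more libraries and at least 30 reads over the 6 libraries. Genes below those numbers were not analysed here. The aggresome libraries held about 4.33 times as many reads outside rRNA as the cytosol libraries did. For protein-coding reads other than those of glpK, rnb and nlpE the ratio was 1.42. Such a minimum therefore admits genes seen in aggresome RNA more readily than genes seen in cytosol RNA. Total counts ran from 15541539 to 22769413 reads in the cytosol libraries and from 7498447 to 8507226 in the aggresome libraries. Outside rRNA they ran from 42027 to 54705 and from 188605 to 222907 reads. A gene with no read in a group was given a floor of 3 reads over that group, and a gene with 1 to 3 reads a ratio with its exact 95% counting interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

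Gene names were matched to a RefSeq gene table of assembly ASM584v2, 1165 by symbol and 3 by synonym. That table was used only for names, gene classes, gene order and coding lengths. Of its coding lengths 99.9% were multiples of 3, so they hold no untranslated regions.

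The count columns were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 1087 tested and 81 untested. Libraries were scaled by trimmed mean of M values (TMM), and the quasi-likelihood test compared the fractions over all 6 libraries with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are aggresome over cytosol, and the standard error is the absolute log2 fold change divided by the square root of the quasi-likelihood F. The TMM factors were 0.412 to 0.468 for the cytosol libraries and 2.22 to 2.34 for the aggresome libraries, a gap that makes the zero point of every fold change a matter of scaling. Fold changes therefore compare shares of RNA between the fractions, relative to a typical gene, and carry no information on molecules per cell. The median log2 fold change of the tested genes was 0.16. The 28 gene lists and the rule for named genes had been fixed before the data were examined, as had the main test. Lists with at least 2 tested members, 26 in all, were tested with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, each with Benjamini-Hochberg adjustment over the lists. With an estimated correlation camera also rests on the few degrees of freedom that 6 libraries leave, so few lists can pass whatever their correlation.

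Named genes were the 12 with the largest fold change in each direction, the 2 members with the smallest adjusted p in the main direction of each list with at least 3 changed members, and the 5 most abundant changed genes per direction. The first set needed full separation of the libraries and a mean of at least 20 reads per library. The largest and the most abundant genes left out rRNA, tRNA and insertion sequence genes, whose reads are shared between copies. The operon arsR, arsB and arsC and the gene hslU were named whatever their values. Genes outside that rule are said to have been chosen after their values were seen.

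Shares of reads were compared by two-sided exact permutation tests of 3 against 3 libraries, which cannot go below p = 0.1. Correlations across genes used Python 3.11.15 with SciPy 1.17.1 and 100000 permutations. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 1.58 to 5.88 between pairs over all genes. Outside rRNA and lacZ it was 1.09 to 1.92. All those pairs differed at an unadjusted 0.05, so each library was counted as 1 replicate. Nothing in the labels says that they came from separate cultures, so the p-values rest only on the spread between these libraries, which may be technical. The test also pooled that spread over genes. The p-values and standard errors of single genes thus reflect little of each gene's own spread over its 3 libraries per fraction. The biological coefficient of variation was 6.53%.

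The test was tried on counts simulated for the 1087 genes from the means and totals of these libraries. It recovered 72% of 100 genes changed 2-fold and 99% of 100 genes changed 4-fold, and called 6 of 887 unchanged genes. The simulation took means over both fractions and 1 common dispersion, with as many genes raised as lowered. It held no shift of composition between the fractions, so it does not test the scaling. Alternatives covered the scaling, the low-count filter, DESeq2 1.42.0 in place of edgeR, stricter thresholds, the replicate number as a block, each library left out, and fits without the rRNA genes or the most abundant other genes.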

Results

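The series followed RNA in Escherichia coli K-12 MG1655, the standard laboratory wild type, after 30 min with sodium arsenite at 37 °C. Aggresomes are protein condensates that bacterial cells form under stress. By its title the study asked whether mRNA is protected in them. Cells were separated after the treatment into aggresome and cytosol fractions, and each fraction gave 3 RNA libraries. The labels do not say whether the libraries came from separate cultures, or whether both fractions came from the same culture. Cytosol libraries 1 to 3 held 15541539, 19692704 and 22769413 reads over the 1168 genes, and aggresome libraries 1 to 3 held 7498447, 8002603 and 8507226.

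The first comparison was of the RNA classes in the fractions. Ribosomal RNA took nearly all reads in both, at 99.8% ± 0.0178 in cytosol RNA and 97.4% ± 0.0667 in aggresome RNA (SD, n = 3 libraries each here and below). The 23S rRNA took 86.9% ± 0.281 of cytosol reads and 67.7% ± 0.143 of aggresome reads, while 16S rRNA took 12.8% ± 0.307 and 29.7% ± 0.190. The ratio of 23S to 16S reads was 6.79 ± 0.186 in the cytosol and 2.28 ± 0.0193 in the aggresome libraries. Protein-coding genes other than glpK, rnb and nlpE held 0.215% ± 0.0144 of cytosol reads and 0.733% ± 0.0338 of aggresome reads, 3.40 times as much. All 43 tested tRNA genes were higher in aggresome RNA, with a median log2 fold change of 2.77, and tRNA took 1.21% ± 0.110 of the reads outside rRNA against 0.366% ± 0.0571. The 10 most abundant genes took 92.5% ± 0.142 of cytosol and 80.9% ± 0.0589 of aggresome reads. Each of these shares separated all aggresome from all cytosol libraries (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 libraries allow). The rRNA and tRNA genes occur in near-identical copies, so values of single copies are uncertain. All 22 rRNA genes were lower relative to other genes under TMM, but with library totals as the only scaling the 16S genes were higher, at log2 fold changes of 1.13 to 1.25, and the 23S genes lower, at -0.45 to -0.31.

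**Figure D1:**
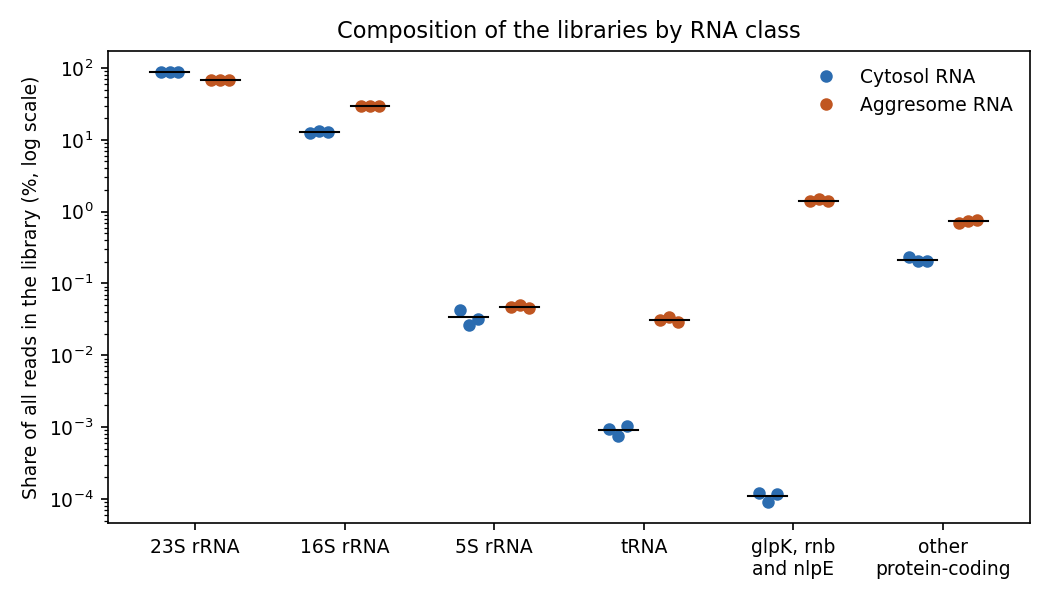
Share of all reads in each library (percent, log axis) taken by 6 classes of RNA, with 1 point per library, cytosol in blue and aggresome in orange, and a line at each mean of 3 libraries. The glpK, rnb and nlpE reads and the tRNA reads differ most between the fractions, and 16S rRNA takes a mean of 12.8% in cytosol and 29.7% in aggresome RNA.

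The second comparison asked which transcripts were held more in aggresome than in cytosol RNA. The genes glpK (glycerol kinase) and rnb (the exoribonuclease RNase II) had the largest fitted fold changes toward aggresome RNA under TMM with all 6 libraries, at log2 fold changes of 11.75 ± 0.15 and 11.17 ± 0.14 (SE, n = 3 libraries per fraction here and below). The gene nlpE, for an outer membrane lipoprotein that signals envelope stress, stood at 8.59 ± 0.17, close to the chromosome condensin gene mukF at 8.58 ± 0.27, which had 2 cytosol reads and lay above nlpE by DESeq2 (8.92 against 8.81). Together glpK, rnb and nlpE made up 54.8% ± 1.77 (SD) of the aggresome reads outside rRNA and 0.0443% ± 0.00560 of the cytosol ones. The gene glpK had 24 reads over the 3 cytosol libraries and 183596 over the 3 aggresome libraries. In the other direction, among genes with a mean of at least 20 reads per library, gabT of 4-aminobutyrate degradation at -5.91 ± 0.36 (-5.30 without aggresome replicate 2) and astB of arginine degradation at -5.87 ± 0.28 (-6.49 without aggresome replicate 3) had the largest fold changes. Of 1087 genes tested, 402 were higher and 346 lower in aggresome RNA by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 348 and 267 of these changed at least 2-fold. The counts rest on the scaling. With library totals alone 949 genes were higher and 67 lower, and with rRNA left out and totals alone 181 were higher and 571 lower. Over the genes tested in both fits these scalings moved the median log2 fold change by 2.38 and by -0.97, and 247 of the 748 calls changed sign in the first, and 46 of the 625 calls tested in the second. The second tested 939 genes, 880 of them shared with the TMM fit, so list medians under it are given below over the shared members, beside the TMM median of those members where a list lost any. With glpK, rnb, nlpE and lacZ also left out of the second, 345 of 912 tested genes were higher and 336 lower, and the median of 863 shared genes moved by 0.19. In 778 of the 1087 genes all aggresome libraries lay on the same side of all cytosol libraries in TMM-scaled level, against 10% by chance for a single gene. The genes are not independent trials, since any difference shared by a whole group of libraries separates many genes at once. This count rests on the scaling as well.

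Among the other genes higher in aggresome RNA were nuoJ, a subunit gene of NADH dehydrogenase I, at 5.70 ± 0.19, the arabinose importer gene araE at 5.39 ± 0.27 (6.04 without cytosol replicate 1) and the ribosomal protein gene rpsC at 5.09 ± 0.36. The gene mukF had 2 cytosol reads, both in replicate 2, and a ratio of 427 (95% counting interval 118 to 3527). The arabinose catabolic gene araD had 1 cytosol read, in replicate 2, and a ratio of 62.4 (11 to 2482). The ribosomal protein genes rplM, rplX and rplC had 3 cytosol reads each and ratios of 39.8 (13.5 to 194), 39.3 (13.3 to 192) and 31.1 (10.5 to 152). Leaving out cytosol replicate 2 left mukF and araD no cytosol read, and leaving out cytosol replicate 3 gave them log2 fold changes of 7.90 and 5.04, from 8.58 and 5.66. The log2 fold change of rplM went from 5.21 to 5.98 without cytosol replicate 3, of rplX from 5.19 to 6.14 without cytosol replicate 1 and of rplC from 4.85 to 5.76 without cytosol replicate 2. The gene ygeA, next to araE, had no cytosol read and was at least 18.4-fold higher, taking the floor of 3 reads over the group. Lower in aggresome RNA were gabD at -5.19 ± 0.27, the arginine degradation genes astD at -4.91 ± 0.26 and astA at -4.77 ± 0.23, and glaH of glutarate degradation at -4.52 ± 0.26. The reductase genes nemA and dkgA stood at -5.12 ± 0.21 and -4.04 ± 0.31, flu, which encodes the surface protein antigen 43, at -4.23 ± 0.34, the sulfate assimilation genes cysI and cysD at -4.39 ± 0.25 and -4.05 ± 0.19, and the acyl-CoA dehydrogenase gene fadE at -3.95 ± 0.11. These lower genes kept their direction with library totals alone, with astA at -2.39, cysD at -1.66 and fadE at -1.56.

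Most abundant among the higher genes, after glpK and rnb, were ssrA, the tmRNA that frees stalled ribosomes, at 1.45 ± 0.08, csrB, an RNA that binds the translation regulator CsrA, at 4.13 ± 0.10, and the arabinose regulator gene araC at 0.73 ± 0.08. With rRNA left out and totals alone, araC stood at -0.24. Most abundant among the lower genes were gatZ and gatY of galactitol use at -3.34 ± 0.09 and -1.56 ± 0.08, the peroxide-induced small RNA oxyS at -2.83 ± 0.09, and the chaperone genes clpB and dnaK at -3.04 ± 0.09 and -1.37 ± 0.09. With library totals alone gatY and dnaK turned positive, at 0.84 and 1.03.

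Of 52 tested ribosomal protein genes 51 were higher in aggresome RNA and none lower, also when adjusted over the list alone, and rpsP was at -0.09 ± 0.46. The median log2 fold change was 3.26, and 5.59 under library totals alone. Over the 48 shared genes it went from 3.30 to 2.35 with rRNA left out and totals alone. Examples were rpsB at 3.66 ± 0.17 and rplO at 3.34 ± 0.21. The list stood apart by camera with Benjamini-Hochberg adjustment over 26 lists (adjusted p = 1.6e-10, and adjusted p = 0.28 with an estimated correlation). The aminoacyl-tRNA synthetases differed from that, with 1 of 19 higher (tyrS, 1.00 ± 0.42, named after its value was seen, and no longer past the threshold without cytosol replicate 1 or 3 or aggresome replicate 2, at 0.94, 0.61 and 0.83) and 7 lower, or 1 and 6 adjusted over the list alone, and with a median of -0.39 that became 1.98 with library totals alone. Their examples ileS and pheT, at -1.68 ± 0.17 and -1.26 ± 0.14, turned to 0.72 and 1.14 with library totals alone. Of 8 genes of RNA polymerase and elongation factors, rpoA (1.51 ± 0.15) and rpoB (0.90 ± 0.20, but -0.07 with rRNA left out and totals alone) were higher, and rpoD, for the housekeeping sigma factor and named after its value was seen, was lower at -1.81 ± 0.13, with the same counts adjusted over the list alone. With library totals alone all 8 genes were higher, rpoD among them. The list's median was 0.30, and over the 7 shared genes it went from 0.27 to -0.70 with rRNA left out and totals alone. By camera with the same adjustment the adjusted p was 0.80 for the synthetases and 0.88 for RNA polymerase.

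Small regulatory and housekeeping RNAs were also mostly higher, 9 of 10, also adjusted over the list alone, and oxyS was the 1 lower member. The list's median was 1.84, 4.23 with library totals alone and 0.87 with rRNA left out and totals alone. Beside csrB, the 6S RNA gene ssrS, whose product binds RNA polymerase, was at 3.40 ± 0.10. The list's adjusted p by camera with Benjamini-Hochberg adjustment was 0.00039, 0.075 with library totals alone, and an adjusted p of 0.29 with an estimated correlation.

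All 14 genes of the TCA cycle were lower in aggresome RNA under TMM, also adjusted over the list alone, with sucA of 2-oxoglutarate dehydrogenase at -3.42 ± 0.12 and the citrate synthase gene gltA at -2.83 ± 0.10. Their median was -2.49, and -0.09 with library totals alone, where 5 were higher and 5 lower. Of 7 tested genes of NADH dehydrogenase I, 5 were lower, among them nuoG at -2.74 ± 0.21 and nuoC at -2.59 ± 0.25, and only nuoJ was higher, for a median of -2.34 that became 0.04 with library totals alone. ATP synthase went the other way, with 6 of 7 genes higher, such as atpB at 3.27 ± 0.53 and atpF at 2.59 ± 0.44 (3.24 without cytosol replicate 3), and atpD, named after its value was seen, lower at -0.76 ± 0.34. The call of atpD was lost without cytosol replicate 1 (-0.64) or 3 (-0.78), without aggresome replicate 1 (-0.59) or 2 (-0.60) and without the low-count filter. With library totals alone all 7 genes were higher, atpD among them. Of the 6 higher genes, atpC (1.89) lost its call without cytosol replicate 1 (1.37) or 3 (1.58). The call of atpE (1.89) was lost without cytosol replicate 2 (1.32). Both were named after their values were seen. Glycolysis was mixed, with 4 of 12 genes lower, among them pgi at -1.34 ± 0.24 and eno at -1.21 ± 0.23, and 2 higher (ptsG, 1.83 ± 0.51, and tpiA, 1.30 ± 0.47, both named after their values were seen). The fold change of ptsG was 2.85 without cytosol replicate 3, and the call of tpiA was lost without cytosol replicate 2 (0.72) or aggresome replicate 2 (1.04). With library totals alone pgi and eno turned to 1.06 and 1.19, and the median of glycolysis from -0.24 to 2.16. For these 3 lists the counts adjusted over the list alone were the same. By camera with Benjamini-Hochberg adjustment the TCA list gave an adjusted p of 6.5e-10 (adjusted p = 0.28 with an estimated correlation), against 0.78 for NADH dehydrogenase I, 0.32 for ATP synthase and 0.92 for glycolysis.

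All 11 tested genes of sulfate assimilation and cysteine synthesis were lower in aggresome RNA under TMM, also adjusted over the list alone, with a median of -3.01 (-0.61 with library totals alone, where 2 were higher and 6 lower). Beside cysD, the thiosulfate-binding protein gene cysP was at -2.67 ± 0.15. All 8 tested genes of iron-sulfur cluster assembly were lower, also adjusted over the list alone, with a median of -2.57 (-0.19 with library totals alone, where 3 were higher and 3 lower), among them sufB at -3.50 ± 0.29 and the cysteine desulfurase gene iscS at -2.23 ± 0.13, which was at 0.17 with library totals alone. By camera with Benjamini-Hochberg adjustment the sulfur list gave an adjusted p of 3.6e-05 (adjusted p = 0.33 with an estimated correlation) and the iron-sulfur list 0.012 (adjusted p = 0.29 with an estimated correlation). The iron-sulfur list's adjusted p was 0.0528 without cytosol replicate 1 and 0.105 without cytosol replicate 3. Of 2 tested genes of methionine synthesis, metK was higher (1.74 ± 0.61) and metH lower (-1.66 ± 0.30), both named after their values were seen, and metK was at 2.44 without cytosol replicate 2 and lost its call without cytosol replicate 3 (1.34). For this list camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.97 with its direction down against a median of 0.04. With library totals alone the median was 2.40 and both genes were higher, metH among them.

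Of 19 heat shock chaperone and protease genes 11 were lower in aggresome RNA under TMM, also adjusted over the list alone, such as the disaggregase gene clpB and the Hsp90 gene htpG (-2.44 ± 0.11). The higher 3, named after their values were seen, were groS at 1.28 ± 0.16, grpE at 0.77 ± 0.15 and rpoH at 0.46 ± 0.17, the last not past the threshold without cytosol replicate 2 (0.42) or 3 (0.36). The list's median was -0.64, but 1.76 with library totals alone, where 16 were higher and 2 lower. The gene hslU, whose protein serves as a marker of aggresomes, was lower at -3.17 ± 0.14 and at -0.78 with library totals alone. Of 13 OxyR and SoxRS regulon genes 10 were lower, also adjusted over the list alone, with a median of -1.26 that became 1.14 with library totals alone, where 10 were higher and 2 lower, among them the aconitase gene acnA at -3.65 ± 0.11 and the catalase gene katG at -2.91 ± 0.09. Its 1 higher member was soxS, the regulator induced by redox cycling drugs, at 3.22 ± 0.54 and named after its value was seen. By camera with Benjamini-Hochberg adjustment the heat shock list gave an adjusted p of 0.011 (0.925 with library totals alone, 0.0697 without aggresome replicate 2, and adjusted p = 0.28 with an estimated correlation) and the OxyR and SoxRS list 0.00085 (0.145 with library totals alone, and adjusted p = 0.29 with an estimated correlation).

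The arsenite resistance operon gave few reads. Its repressor gene arsR was lower in aggresome RNA at -2.35 ± 0.37, but at 0.03 with library totals alone, and the low-count filter removed it when any 1 cytosol library was left out. The efflux pump gene arsB had 46 cytosol and 15 aggresome reads and was not tested in the main comparison. It was lower without the filter (-2.61 ± 0.42), without the rRNA genes (-2.44 ± 0.40) and by DESeq2 (-2.57 ± 0.56). The authors' deposited table called it lower at the same -2.57, so that call adds no separate support. The gene arsC was not analysed here. Of the 5 tested genes for arsenic and metal efflux, arsR was the 1 lower member, also adjusted over the list alone, and the copper exporter gene copA (0.74 ± 0.27) and the zinc-binding gene zraP (0.89 ± 0.38) passed as higher, at -0.23 and -0.07 with rRNA left out and totals alone. Neither call held in every fit with a library left out. The call of copA was lost without cytosol replicate 2 (0.55). That of zraP was lost without cytosol replicate 2 (0.88) or 3 (0.33) or aggresome replicate 2 (0.80), and its fold change was 1.51 without cytosol replicate 1. The cytosol and aggresome libraries of zraP were not fully separated in level. The authors' deposited table called both genes not changed, with copA at 0.93 and zraP at 1.05. No call in it lay under an absolute log2 fold change of 1.01, so copA fell under a limit that was not set here. The list's median was 0.44 and its mean -0.18, and the median was 2.80 with library totals alone. Over the 4 shared genes, which leave out arsB and cueO, it went from 0.05 to -0.92 with rRNA left out and totals alone. For this list camera with Benjamini-Hochberg adjustment gave an adjusted p of 0.98.

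Of 49 genes listed for flagella and chemotaxis 12 were tested. Among these, 10 were higher in aggresome RNA and none lower, also adjusted over the list alone. Their median was 2.56, or 4.89 with library totals alone. Only 4 of the 12 were tested with rRNA left out, and with totals alone their median went from 3.66 to 2.73. Of the 251 coding genes in the lowest quartile of mean level, 146 were higher and 1 lower. Genes with few reads were thus seldom called lower. The flagellin gene fliC was at 3.61 ± 0.27, and the motor gene motA had 1 cytosol read and a ratio of 26.9 (95% counting interval 4.64 to 1079). Its log2 fold change of 4.46 was 3.84 without cytosol replicate 3, and without cytosol replicate 1 no cytosol read was left. The list did not pass by camera with Benjamini-Hochberg adjustment, at an adjusted p of 0.075 (0.42 with an estimated correlation), which was 0.0194 without aggresome replicate 1 and 0.00702 without aggresome replicate 2. All 6 tested cold shock genes were higher, also adjusted over the list alone, with cspE at 1.08 ± 0.10 and cspD at 1.09 ± 0.15, and their median was 1.08. Over the 5 shared genes it went from 1.08 to 0.11 with rRNA left out and totals alone. Their adjusted p by camera with Benjamini-Hochberg adjustment was 0.15, and 0.0477 without aggresome replicate 2.

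Envelope genes went in both directions. Of 12 genes of fatty acid and phospholipid synthesis 7 were higher and none lower, such as acpP, for the acyl carrier protein, at 2.18 ± 0.20 and fabB at 1.6 ± 0.25, with a median of 1.27, and over the 10 shared genes 1.38, or 0.42 with rRNA left out and totals alone. Of 10 genes of protein export 5 were higher and none lower, among them secY at 1.81 ± 0.12 and secG at 3.90 ± 0.42 (4.60 without cytosol replicate 2), with a median of 0.93, and over the 6 shared genes 0.30, or -0.66 with rRNA left out and totals alone. Of 15 outer membrane genes 3 were higher and 5 lower, with the fatty acid porin gene fadL at -3.07 ± 0.18 and ompA at -0.95 ± 0.09, and ompA was at 1.45 with library totals alone. The higher 3, named after their values were seen, were lpp at 1.29 ± 0.13, ompF at 1.52 ± 0.14 and ompC at 0.64 ± 0.13. Inner membrane transporters, a list set to follow membrane carried along with a fraction, had 4 of 14 higher and 5 lower, with the oligopeptide transporter genes oppB and oppC at -2.99 ± 0.21 and -3.29 ± 0.31 and a median of -0.32 that became 2.07 with library totals alone. Of 9 genes of cell division and peptidoglycan synthesis mreB (2.39 ± 0.51) and mrcB (1.42 ± 0.59) were higher and ftsA, named after its value was seen, lower at -0.59 ± 0.21. The call of ftsA was lost without cytosol replicate 2 (-0.41), and that of mrcB without cytosol replicate 2 (1.10) or 3 (1.26) or aggresome replicate 2 (1.42). With library totals alone all 9 genes were higher, ftsA among them. The authors' deposited table called mrcB not changed. The median of this list was 0.30, and over the 8 shared genes 0.19, or -0.78 with rRNA left out and totals alone. Adjusted over the list alone 1 of these genes was higher and 1 lower, and the other lists of this paragraph gave the same counts. By camera with Benjamini-Hochberg adjustment the adjusted p was 0.32 for fatty acid synthesis, 0.32 for export, 0.98 for outer membrane genes, 0.80 for inner membrane transporters and 0.80 for cell division.

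Of 7 ribonuclease and RNA decay genes rnb, the RNA chaperone gene hfq (0.98 ± 0.21) and pnp (0.57 ± 0.16) were higher, and rne, for RNase E, was lower at -3.21 ± 0.16. Of 10 RpoS general stress genes 6 were higher, or 7 adjusted over the list alone, among them osmE at 1.56 ± 0.21 and wrbA at 1.21 ± 0.14, and poxB was lower at -2.72 ± 0.24. Among 4 toxin-antitoxin genes dinJ (2.03 ± 0.34) and mqsR (1.07 ± 0.21) were higher and yefM lower (-0.89 ± 0.40). Of 9 genes of branched-chain and aromatic amino acid synthesis trpE (3.77 ± 0.44), trpD (3.05 ± 0.50) and trpC (1.10 ± 0.43) were higher, and ilvB (-2.30 ± 0.27) and pheA (-0.99 ± 0.22) lower. The genes trpE and trpD had 5 cytosol reads each, and without cytosol replicate 1 they stood at 4.51 and 4.70, with trpD at 2.34 without cytosol replicate 3. The call of trpC was lost without cytosol replicate 1 (0.68) or 3 (0.61), and it was at 2.59 without replicate 2. The call of yefM was lost without cytosol replicate 3 (-0.63) or aggresome replicate 1 (-0.82) or 2 (-0.63), and without the low-count filter. With library totals alone all 4 toxin-antitoxin genes were higher, yefM among them. Of 6 SOS genes uvrA (-1.36 ± 0.24) and uvrB (-1.76 ± 0.34) were lower. Except for RpoS the counts adjusted over the list alone were the same. In this paragraph pnp, rne, poxB, yefM, trpC, ilvB, pheA, uvrA and uvrB were named after their values were seen. The medians of the ribonuclease, RpoS, toxin-antitoxin, amino acid and SOS lists were 0.52, 0.81, 0.55, 0.82 and 0.02. With rRNA left out and totals alone those of the ribonuclease and toxin-antitoxin lists, which kept all members, were -0.44 and -0.42. Over the shared members it went from 0.72 to -0.24 for 9 RpoS genes, from 0.82 to -0.14 for 7 amino acid genes and from -0.27 to -1.24 for 5 SOS genes. The SOS median was 2.42 with library totals alone. In that fit 9 of 10 RpoS, 8 of 9 amino acid and 5 of 6 SOS genes were higher and 0 lower. By camera with Benjamini-Hochberg adjustment the adjusted p was 0.32, 0.57, 0.78, 0.83 and 0.92 for these lists in order. The 1 tested gene of histidine and arginine synthesis did not pass, and no gene of iron uptake was analysed here. By camera 7 of the 26 lists passed, and with an estimated correlation 0 did, with 3 at an unadjusted p under 0.05. That loss is not a measure of correlation between genes. The heat shock list's estimated correlation was -0.047, below the preset 0.01, yet its unadjusted p by camera went from 0.0025 to 0.030. By fry, which asks only whether a list's own genes differ from 0 on average under TMM, 20 lists passed.

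**Figure D2:**
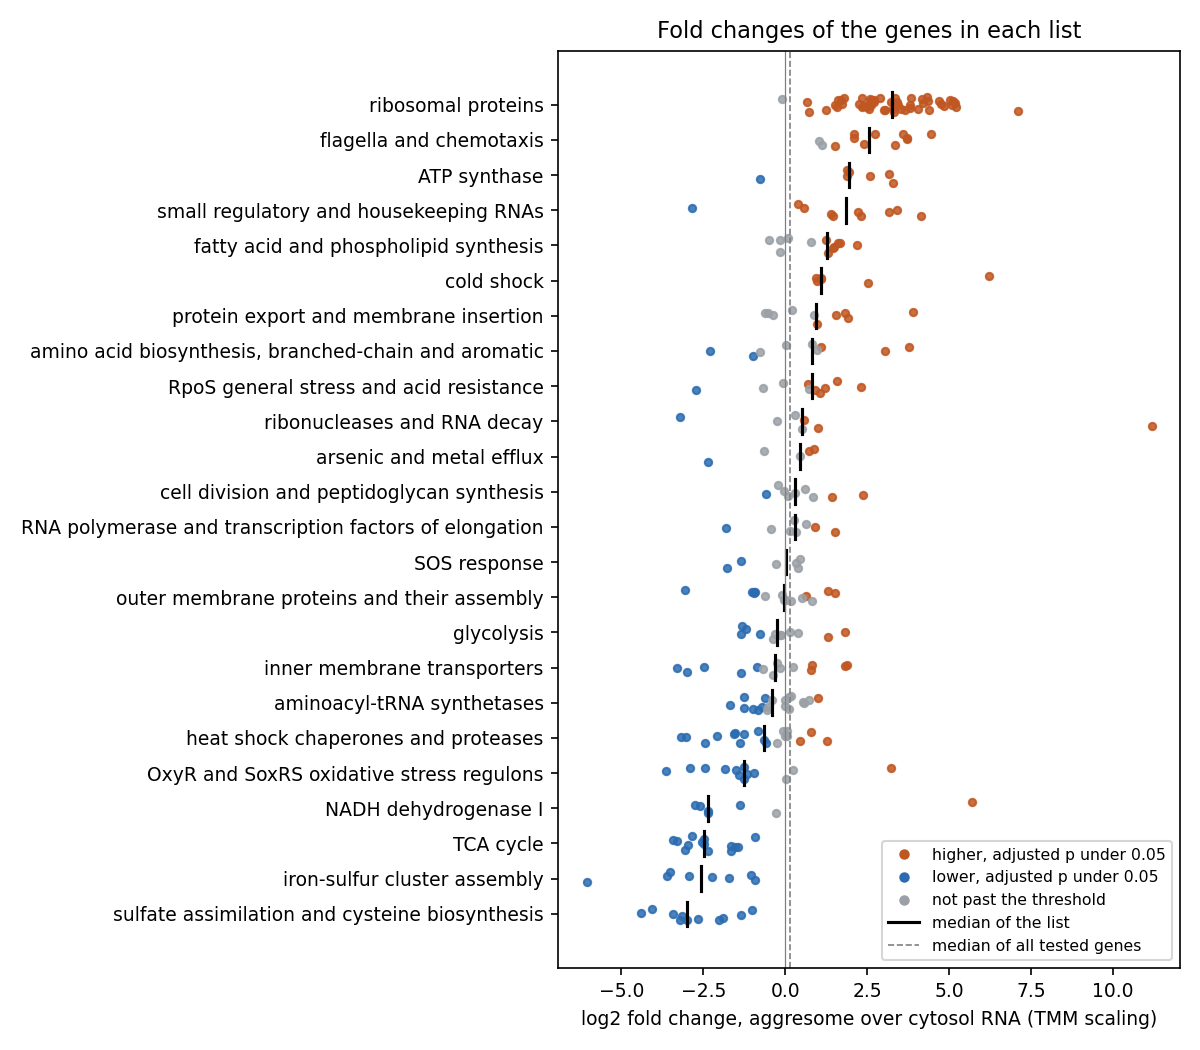
Log2 fold change (aggresome over cytosol RNA, TMM scaling) of each tested gene in the lists with at least 5 tested members, colored by the result of the edgeR test, with a black line at each list's median and a dashed line at 0.16, the median of all tested genes. Ribosomal protein genes center on 3.26 and TCA cycle genes on -2.49, which became -0.09 with library totals alone, and the lone point at 11.17 is rnb.

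The third comparison asked whether coding length and level went with the difference. Shorter genes were higher in aggresome RNA. Across 1002 protein-coding genes, which are not independent replicates, Spearman's rho of log2 fold change and coding length was -0.33 and Pearson's r with log2 length -0.30 (permutation p = 1e-05 for rho, the smallest that 100000 permutations can give). Genes of 60 to 510 nt had a median log2 fold change of 0.93, and 54.0% of them were higher. Medians for the next quartiles were 0.22 and -0.27, and genes of 1404 to 4962 nt had a median of -0.51, with 21.2% higher. Within single libraries the rho of level and length was 0.236 ± 0.00451 in cytosol and -0.0716 ± 0.0153 in aggresome RNA (SD, n = 3, two-sided exact permutation p = 0.1, the smallest possible). Against mean level the rho was -0.48, but it was -0.71 when level came from cytosol library 1 alone and 0.18 when it came from aggresome library 1 alone, so no direction is given.

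**Figure D3:**
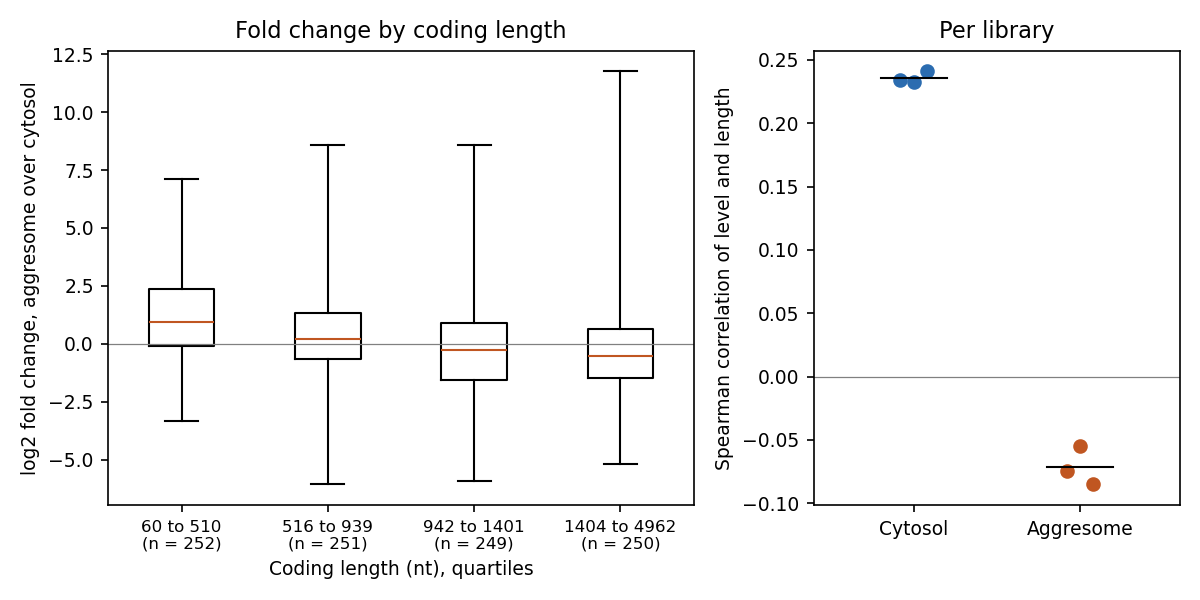
Left, log2 fold change (aggresome over cytosol) of protein-coding genes by quartile of coding length in nt, with boxes from the lower to the upper quartile, an orange line at the median and whiskers to the lowest and highest gene. Right, Spearman correlation of level and coding length across genes within each library, with a line at each mean of 3 libraries, 0.236 for cytosol and -0.0716 for aggresome RNA.

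The authors' deposited table called 341 genes higher and 281 lower in aggresome RNA and 546 not changed. Of the genes in the authors' deposited table, 375 and 322 had an adjusted p under 0.05, and every called gene also had an absolute log2 fold change of at least 1.01. Of its 622 calls 569 passed here in the same direction, and the other 53 were not tested here because of their low counts. All 748 genes past the threshold here had the same sign as in the authors' deposited table. Both rest on the same counts, so the shared calls and signs are not independent support.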

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

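The tests of neighbouring genes and of the scaling were chosen after the result was seen. The gene lacZ, for beta-galactosidase, had 2407 reads in aggresome replicate 3, against 6 and 0 in aggresome replicates 1 and 2 and 2, 3 and 2 in the cytosol libraries. It stood out as a signal in a gene outside the tests, since the low-count filter had removed it, and the authors' deposited table gave it no adjusted p. The neighbouring repressor gene lacI had 64 reads in the same library, and 2 and 10 in the other aggresome libraries. Despite that spread lacI was called lower in aggresome RNA, at -0.65 (edgeR's quasi-likelihood test, adjusted p = 0.036).

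The genes glpK, rnb and nlpE had 2863 or more reads in each aggresome library and 24, 29 and 11 reads in all cytosol libraries together. A raised level of the region around each gene is argued against, since the 5 measured genes within 2 places of them had a median log2 fold change of -0.15, and glpF, of the same operon as glpK, had 35 aggresome and 14 cytosol reads. Under TMM, which trims such genes, leaving out glpK, rnb, nlpE and lacZ lost or turned 0.0% of the other 745 calls, which decides little, but with rRNA left out and totals alone it moved the counts from 181 higher and 571 lower to 345 and 336. An untested candidate explanation is that reads from another abundant sequence were counted at these genes, which read positions would show and the table holds none. Retention of these transcripts in aggresomes stays open as a hypothesis, untested for the same reason. The genes nuoJ and mukF, with 1850 and 1874 aggresome reads and 16 and 2 cytosol reads, also stood apart from genes near them. The only measured genes within 2 places were nuoL at -1.37 and mukB at -0.51. Both candidates, miscounted reads and retention, stay untested for nuoJ and mukF as well.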

How the results depend on the processing

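Fits without the rRNA genes, without rRNA and tRNA genes, and without glpK, rnb, nlpE and lacZ, with and without rRNA, and level from aggresome library 1 were chosen after seeing the data. Those on length without ribosomal protein genes or with at least 50 reads were not planned, but were chosen before their own results were seen. The 402 higher and 346 lower genes became 949 and 67 with library totals alone, where 247 calls turned sign and the median log2 fold change was 2.54, a shift of 2.38. With rRNA left out and totals alone they were 181 and 571, with a median of -1.18 over 939 genes and a shift of -0.97 over the 880 shared ones, by construction in part, since glpK, rnb and nlpE hold 54.8% of the aggresome reads outside rRNA. Leaving those and lacZ out as well gave 345 and 336, with a shift of 0.19 over 863 shared genes. RLE scaling gave 432 and 327 with a shift of 0.11, no filter 421 and 370, DESeq2 375 and 322, a fit without rRNA genes 349 and 330, without rRNA and tRNA genes 331 and 317, and without glpK, rnb, nlpE and lacZ 399 and 347. An adjusted p under 0.01 left 352 and 316. Leaving out each library gave 356 to 407 higher and 317 to 371 lower. With the replicate number as a block 397 were higher and 344 lower, and the block changed no list's call and no named gene's call. Whether the numbers pair the libraries stays open, with deviations of same-numbered libraries correlated at 0.008 to 0.069 over 486 genes, and 4 of 6 libraries correlated best with their own number, which is a hint from the data and not the design.

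Genes named by the fixed rule that turned sign with library totals alone were iscS (0.17), pgi (1.06), eno (1.19), ileS (0.72), pheT (1.14), ompA (1.45), gatY (0.84), dnaK (1.03) and arsR (0.028), and with rRNA left out and totals alone copA (-0.23), zraP (-0.072), rpoB (-0.072) and araC (-0.24). No other fit turned a gene named by that rule. Genes named after their values were seen, such as rpoD, atpD, metH, ftsA and yefM, also turned from lower to higher with library totals alone. DESeq2 lost 2 of 78 named calls, library totals alone 4, totals with rRNA left out 5, and leaving out a library at most 3.

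For the lists, camera with an estimated correlation gave an adjusted p of 0.284 for ribosomal proteins, heat shock and the TCA cycle, 0.295 for the OxyR and SoxRS, iron-sulfur and small RNA lists and 0.333 for sulfate assimilation, all past the threshold with the preset one. With library totals alone heat shock (0.925), OxyR and SoxRS (0.145) and small RNAs (0.0752) no longer passed. With a library left out the adjusted p ran from 0.00519 to 0.0697 for heat shock (highest without aggresome replicate 2), 0.00241 to 0.105 for iron-sulfur assembly (0.0528 without cytosol replicate 1, highest without cytosol replicate 3), 0.00702 to 0.146 for flagella (0.0194 without aggresome replicate 1, lowest without aggresome replicate 2) and 0.0477 to 0.297 for cold shock (lowest without aggresome replicate 2). Without glpK, rnb, nlpE and lacZ the flagellar list passed at 0.0443. By fry, which asks another question, lists not past by camera gave 0.0138 for methionine, 8.89e-05 for ribonucleases, 0.000194 for flagella, 0.00751 for NADH dehydrogenase I, 0.000323 for ATP synthase, 0.00104 for aminoacyl-tRNA synthetases, 0.0029 for RpoS genes, 0.00067 for export and also for cold shock, 0.0253 for cell division, 0.00082 for toxin-antitoxin genes, 0.000836 for inner membrane transporters and 0.000318 for fatty acid synthesis. A pass by fry does not mean that the members moved one way. The methionine list had 1 gene higher and 1 lower, and the transporter list 4 higher and 5 lower. The ribonuclease list includes rnb.

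The correlation with length of -0.33 was -0.297 given the level, -0.298 without genes under 300 nt, -0.272 without ribosomal protein genes and -0.375 with at least 50 reads. That with level was -0.714 or 0.184 with level from cytosol or aggresome library 1, and -0.565 to -0.393 with a library left out. The cause was not tested for any of these changes. The pseudocount, the filter on normalized values and quantile normalization were not run, since the table holds counts. Depth limits the cytosol side most, with at most 54705 reads outside rRNA.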

Other observations

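The arabinose test and the count of regrouped libraries were chosen after the result was seen, as were the bounds for the planned partial correlation of length given level, and the operon groups below after their values were seen. All 8 genes of fatty acid degradation were lower under TMM, with log2 fold changes from -3.95 to -2.63 and a median of -3.24, or -0.84 with library totals alone. All 4 tested genes of arginine succinylation, astA to astD, had a median of -4.84, or -2.46 with library totals alone, and gabD, gabT, glaH and lhgD of 4-aminobutyrate and glutarate degradation a median of -4.85, or -2.48. The oligopeptide importer genes oppA to oppF had a median of -2.97, or -0.58 with library totals alone, where 3 were lower and 1 higher. The higher gene was oppA, the member with the most reads, at -1.39 under TMM and 1.00 with library totals alone. The 6 galactitol genes had a median of -1.93 under TMM and of 0.47 with library totals alone.

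Among 5S rRNA genes rrfA and rrfB stood at -0.91 ± 0.09 and -0.95 ± 0.09 (SE, n = 3 libraries per fraction), against -2.66 to -2.01 for the other 6, although the copies are near-identical. Of 13 tested noncoding RNA genes other than rRNA and tRNA 11 were higher and 2, oxyS and ryjA (-1.88 ± 0.20), were lower under TMM. With rRNA left out and totals alone 8 of 12 lay above 0 and 4 below. The gene ryjA was chosen after its value was seen.

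The 748 genes past the threshold came from 1 of the 10 splits of the 6 libraries into groups of 3. The highest count of the other splits was 0 by edgeR's quasi-likelihood test, with 0 to 7 genes at an unadjusted p under 0.05. So few splits cannot give a share under 0.05.

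The first pattern weighed here was that shorter coding genes were higher in aggresome RNA. Ribosomal protein genes alone and genes with few reads are each argued against as the whole cause. The rho was -0.27 over 950 genes without ribosomal protein genes and -0.38 over 191 genes with a mean of at least 50 reads. Given the mean level it was -0.30, which cannot decide on a difference in level. That level comes from the same 6 libraries as the fold change. Its own correlation with fold change was -0.71 by cytosol library 1 and 0.18 by aggresome library 1. Among 282 pairs of adjacent genes the shorter was the higher in 57.1% (two-sided binomial p = 0.020), between the bounds set beforehand for and against an effect of each gene's own length. That p takes the pairs as independent. Fold changes of adjacent genes went together (rho 0.57), and pairs may share a gene or a transcript, so it may be too small. Recovery of short or fragmented RNA that differs between the fractions may account for the pattern, as may retention by length in aggresomes, and fragment sizes, which would part them, were not analysed here.

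The second pattern was the arabinose genes, with all 8 measured genes higher under TMM, although araC was at -0.24 with rRNA left out and totals alone. The 7 other than araC had a median log2 fold change of 5.11, or 4.52 with ygeA at its bound. Of these 7 genes 3 had 0 or 1 cytosol read, and araF, with 38 cytosol and 1930 aggresome reads, was at 4.52 ± 0.16. The arabinose genes araB and araA, next to araC, were not analysed here. Whether they were higher as well is not known, so the regulon was seen only in part. A candidate explanation is that cultures behind the aggresome libraries had been given arabinose and those behind the cytosol libraries had not, and the lower catabolic and TCA genes and higher ribosomal protein genes may then reflect the cultures as well. This and retention in aggresomes cannot be told apart for these 7 genes, since the labels do not say which cultures gave which fraction.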
